A study of Lactococcus cremoris with 2 samples.

How the data were processed

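RNA was sequenced from 2 cultures of *Lactococcus cremoris* KW2, 1 with a plasmid for constitutive ComX and 1 with the empty vector. Per the labels' protocols, total RNA was treated with DNase and depleted of rRNA, and directional libraries with inserts of 130 to 580 bp were made. Bowtie2 2.2.3, SAMtools 0.1.19, HTSeq 0.6.1, DESeq2 1.8.1 and edgeR 3.10.2 are the tools of the authors, per the labels. The genome build, and whether the counting used the strand, are not given in the sources used here.

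The deposited data were 3 tables of the authors' own comparison, made with DESeq2, DEXUS and edgeR per the file headers. The authors' DESeq2 table holds a signal per gene, the mean of the size-factor scaled counts of both libraries. It also holds log2 fold changes with standard errors, fold changes, a test score and raw and adjusted p-values, per the file headers. The authors' edgeR table holds log2 fold changes, fold changes, the log2 of the mean depth-scaled counts and raw and adjusted p-values. The deposited DEXUS table holds a mean scaled count per condition, an informative score, an unadjusted p-value, a log fold change and a fold change. Comparison with the means showed that the deposited DEXUS log fold change is a natural log of condition 1 over condition 2. The fold change in the same deposited table is 2 to the power of that natural log, so it is not the ratio of the means, and it was not used.

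The scaled count per condition was the measurement used here. With 1 library per condition, each value is that library's read count divided by a size factor, and 100% of the values were whole multiples of 1 step per library within 0.01. A step is 1 read, worth 1.28 scaled counts in condition 1 and 0.782 in condition 2. A gene with 0 reads is written as 0.5 in the deposited table, in 67 genes of condition 1 and 1 of condition 2, and was set back to 0. The 17 genes that the table does not divide between the conditions were divided from their mean. Dividing by the step gave the reads, 1465873 and 1371768 in all. Because of the floor at 0.5 these were not treated as deposited counts, and no count model was run on them. The design foresaw a count table, TMM scaling as an alternative and a ratio of the ComX library over the control. The comparison tables did not allow these, so TMM was not run and the ratio is condition 1 over condition 2. The tables had 0 columns for other samples.

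No sample was assigned from its values. The deposited assignment columns give condition number 2 to the ComX library and 1 to the control, and no fold change column names its numerator. The late competence genes were higher in condition 1, and the text therefore keeps the condition numbers.

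The log2 ratio of each gene was log2 of the condition 1 value plus 1 over the condition 2 value plus 1, which understates the change of genes with few reads. Genes entered where the larger scaled count was at least 20. With 1 library per strain no test was possible, and genes were counted at 2-fold and 4-fold by size. Folds printed in the text are ratios of scaled counts without a pseudocount, with exact 95% Clopper-Pearson intervals from the reads of both libraries. Where 1 library had 0 reads, the fold is a lower bound against 3 reads in that library. That bound takes the reads of the other library as given, and the exact interval reaches lower, to 37.0-fold for kw2_1430. Reads without molecular identifiers are not independent molecules, so intervals and bounds of folds cover counting error only.

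Gene names, lengths, biotypes and the order of neighbours came from the RefSeq table of assembly ASM46895v1, matched by old locus tag. 2330 of 2349 tags matched and 572 had a symbol. No coordinates are printed because the authors' build is not given. No genome sequence was used, so the planned search for the ComX binding motif was not run. The reference has no product names, so the gene lists could be matched by symbol only. The lists for ComX itself, mannitol use, prophage genes and transposases had no matched member and give no result. The lists of ribosomal proteins and aminoacyl-tRNA synthetases were matched by symbol pattern and tRNA genes by biotype, both chosen after seeing the data. List medians were placed among 10000 random lists of the same size, matched on mean level in 10 bins, as a description of these 2 libraries.

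The gene lists, except those named as added, and the rule for naming genes were fixed before the data were examined. The genes named are the measured members of the competence lists, the 15 highest and 10 lowest log2 ratios, and the 2 largest ratios of each other list. Other genes are named as members of a list or run, or as genes 2-fold apart after an added setting, and these were chosen after their values were seen. Runs were at least 3 genes with consecutive tags at 2-fold in 1 direction, compared with 10000 shuffles. Strand was not used.

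The alternatives set out in advance were total-count scaling, pseudocounts of 0.5 and 5, no minimum or a minimum of 100, the authors' log2 fold changes, stricter adjusted p-values and other run definitions. Alternatives added after seeing the data dealt with background reads. The median reads per kb of condition 2 over 225 genes with the fewest condition 1 reads per kb, times coding length, was either subtracted from condition 2 or added to condition 1. In both cases the scaling was redone, and only genes of the main set with a length were used. The scaling that goes with the added background was also run alone. A further setting subtracted the running median over the 100 genes on either side, ordered by mean level.

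The steps were tested on simulated data drawn from the means of these 2 libraries, with 200 of 2263 genes changed. All 4-fold changes (100%) and 45.5% of 2-fold changes passed the 2-fold rule, as did 0.15% of unchanged genes. These simulated libraries held counting error only, without variation between cultures, background reads or a trend with level. The 0.15% is therefore not the rate of false calls in the real libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.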

Results

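Transcript levels were measured by RNA sequencing in *Lactococcus cremoris* KW2, a lactic acid bacterium. One strain carried a plasmid that makes ComX constitutively, and the control strain carried the empty vector. ComX is the sigma factor that directs RNA polymerase to the late competence genes, which encode the machinery for taking up and recombining DNA. Both strains were grown in chemically defined medium with 5% mannitol and harvested at an optical density of about 0.3. There was 1 library per strain, so no difference below has a replicate check, and no p-value was computed for this comparison.

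The authors' tables give 1 scaled read count per gene and library, under the names condition 1 and condition 2. They held 2349 genes, with 1465873 reads in condition 1 and 1371768 reads in condition 2. The assignment columns of the authors' deposited table give number 2 to the ComX library and number 1 to the control library for 2332 genes. The late competence genes were nevertheless far higher in condition 1. No table names the numerator of its fold changes, and no row carries the symbol comX, so the plasmid gene itself could not be used as a check of the labels. Every direction below is therefore given as condition 1 against condition 2, and not as ComX against control. Intervals of folds are exact 95% Clopper-Pearson intervals on the reads of both libraries and cover counting error only.

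The question of the design was which genes differ when ComX is made all the time. The comG genes, which encode the pilus that binds DNA at the cell surface, had the highest median ratio of the gene lists that were higher in condition 1. All 7 measured genes of the late competence list, comGA to comGG, were at least 2-fold higher in condition 1. comGF, a minor pilin gene, was 30.9-fold higher (23.7 to 40.9) with 1094 reads against 58. comGD was 14.9-fold higher (12.6 to 17.7), and comGC, the gene of the major pilin, was 12.6-fold higher (8.22 to 20.2). comGE rested on 26 reads against 3, a ratio of 14.2 (4.35 to 73.2). comGA, the gene of the assembly ATPase, and comGB, the gene of the membrane platform, were 4.40-fold (3.69 to 5.27) and 4.10-fold (3.44 to 4.91) higher. comGG was 2.42-fold higher (1.61 to 3.66). The list's median log2 ratio was 3.36, above each of 10000 random lists of the same size matched on mean level. The 7 genes lie in a row, kw2_2179 to kw2_2185, so they are not independent measurements.

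Genes that handle the incoming single strand were also higher in condition 1, where 5 of the 7 measured members passed 2-fold. radA, whose helicase extends the strand during recombination, was 20.6-fold higher (18.7 to 22.7), with 5937 reads against 472. dprA, whose product loads RecA on single-stranded DNA, was 9.62-fold higher (7.83 to 11.9). radC was 3.99-fold higher (3.19 to 5.02), and recA, the gene of the strand exchange protein, was 3.49-fold higher (3.26 to 3.74). recX, a modulator of RecA, was 2.24-fold higher (2.12 to 2.36). recR had a ratio of 1.51 and recO a ratio of 0.799. The list's median log2 ratio of 1.803 lay at percentile 99.99 of the matched random lists. Relative to genes of the same mean level, the excess of recX was 0.036 and that of recA 0.72 on the log2 scale, against 3.25 for radA and 2.67 for dprA. With scaling by total count, and with either treatment of background reads described below, 3 of the 7 genes passed 2-fold.

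**Figure D1:**
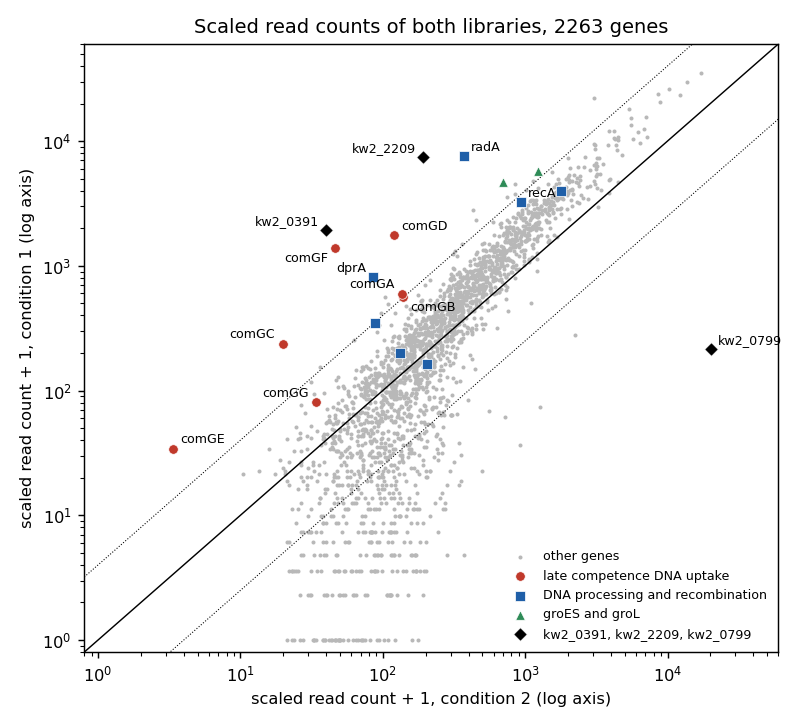
Scaled read counts plus 1 of 2263 genes in condition 2 (x, log axis) and condition 1 (y, log axis), with 1 library each. The solid line marks equal values and the dotted lines a 4-fold difference. Red marks the late competence list, blue the DNA processing list and green groES and groL. comGA to comGF, radA, dprA, groES, groL, kw2_0391 and kw2_2209 lie above the upper dotted line. kw2_0799 (black), at 212 against 20066 scaled counts, lies far below the lower one.

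Of the regulators and Clp proteins known to act on competence in related bacteria, 3 of 5 measured genes were at least 2-fold higher in condition 1. codY, the gene of a repressor of amino acid metabolism, had a ratio of 2.37. clpX, the unfoldase gene of the ClpXP protease, had a ratio of 2.14. Of the 2 genes with the symbol spx, kw2_0494 had a ratio of 2.08 and kw2_0616 of 1.53. clpB, a disaggregase gene, had a ratio of 1.32. The list's median log2 ratio of 1.05 lay at percentile 84.7 of the matched lists, so it did not stand apart from other genes of the same level. None of the 5 passed 2-fold with scaling by total count or with either treatment of background reads described below.

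Several of the largest ratios belonged to genes with no symbol in the reference. kw2_0391 was 49.5-fold higher in condition 1 (37.3 to 66.9; 1511 reads against 50), the largest ratio of all 2263 genes kept. kw2_2209 was 38.7-fold higher (34.0 to 44.1; 5789 reads against 245). The neighbours kw2_1964, kw2_1965 and kw2_1966 were 5.29-fold, 6.44-fold and 7.21-fold higher, and kw2_1966 alone held 17194 reads in condition 1. groES and groL, which encode the chaperonin and follow kw2_0391 in tag order, were 6.76-fold (6.28 to 7.29) and 4.71-fold (4.44 to 4.99) higher. pepF, an oligopeptidase gene, was 5.10-fold higher and its neighbour kw2_1705 5.45-fold. ffh, the gene of the protein part of the signal recognition particle, was 4.83-fold higher.

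**Figure D2:**
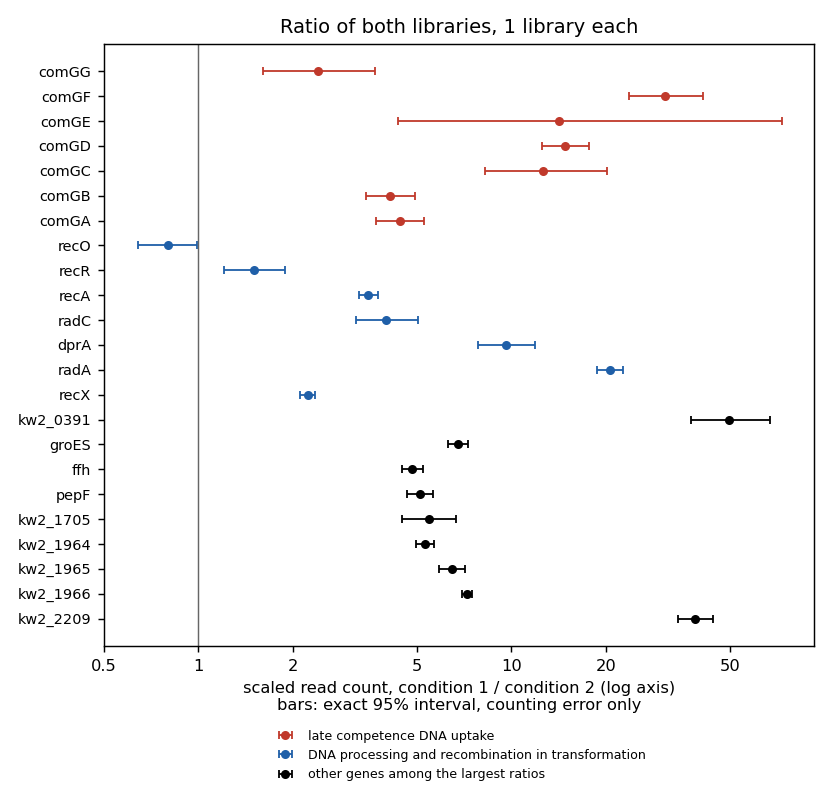
Ratio of the scaled read counts, condition 1 over condition 2 (x, log axis), of the late competence list, the DNA processing list and the other genes among the 15 largest ratios. Points are single ratios of 1 library each and bars are exact 95% intervals for counting error. The interval of recO, from 0.641 to 0.992, lies below 1, and kw2_0391 has the largest ratio, 49.5.

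Over all 2263 genes with a scaled count of at least 20 in either library, 371 were at least 2-fold higher and 552 at least 2-fold lower in condition 1. At 4-fold the numbers were 27 and 358. With scaling by total count in place of the authors' size factors, 38 genes were at least 2-fold higher and 844 lower. That scaling shifts the log2 ratios of genes with many reads in both libraries by -0.81, and those of genes near 0 by less because of the pseudocount, whereas the median over all kept genes was 0.24 with the authors' scaling. comGA to comGF, radA, dprA and radC stayed above 2-fold, but recA at 0.997, comGG at 0.46, recX at 0.36, codY at 0.44, clpX at 0.29 and the spx gene kw2_0494 at 0.25 on the log2 scale did not. recO was then 2-fold lower at -1.12, recR turned to -0.21, the other spx gene, kw2_0616, to -0.19 and clpB to -0.41. The ratio also depended on the level of the gene. The median log2 ratio was -2.12 in the 10% of genes with the lowest mean level and increased in each of the 10 groups to 1.096 in the 10% with the highest. The random lists were therefore matched on level.

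Of the 552 lower genes, 168, 140 and 117 lay in the 3 groups of lowest mean level. The 10 lowest log2 ratios included 8 genes with 0 reads in condition 1 and 103 to 225 reads in condition 2. The count of 0 allows up to 3 reads, which makes kw2_1430 at least 45.8-fold lower, kw2_1593 at least 41.4-fold, essB, a type VII secretion gene, at least 31.4-fold, kw2_1932 at least 27.9-fold and xylB, a xylulokinase gene, at least 26.5-fold. kw2_1264, kw2_1455 and kw2_1452 were at least 24.4-fold, 23.6-fold and 21.0-fold lower. kw2_2127 had 1 read against 245, a 150-fold difference with an interval from 26.6 to 5938. These 9 genes are among the 225 that set the background described next, and adding it to condition 1 brings their log2 ratios near 0 by construction, between -0.45 in kw2_1452 and 0.56 in xylB. kw2_0799 was of another kind, with 166 reads against 25668, and was 94.5-fold lower in condition 1 (81.1 to 111). It had more reads than any other gene of condition 2, and its tag has no match in the reference. Its log2 fold change was -6.68 in the authors' deposited table from edgeR but -0.87 in that from DESeq2, whose values are shrunken.

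Genes close to 0 in condition 1 carried reads in condition 2 that increased with their length. In the 225 protein-coding genes with the fewest condition 1 reads per kb of coding length, the median was 4.53 reads per kb in condition 1 and 128 in condition 2. The quartiles in condition 2 were 93.3 and 161, so the reads were not in strict proportion to length. The low condition 1 value follows from how these genes were chosen, and no set chosen by condition 2 was compared. The condition 2 median was taken as a background per kb, the same for every gene. When the same background per kb was added to condition 1, 54 genes were at least 2-fold higher and 53 lower, among 2251 genes with a length. This setting, called the equal background, also rescales the libraries, which shifts the log2 ratios of genes with many reads in both libraries by -1.06. The rescaling alone gave 22 higher and 975 lower genes, so the fall in the number of higher genes came with the rescaling and the fall in the number of lower genes with the added background. With the rescaling alone the medians of the regulator, DNA damage, synthetase, purine, pyrimidine, fatty acid and cell wall lists were below 0. Of the 53, 27 were protein-coding and 26 were tRNA or rRNA genes. The background per kb was set on protein-coding genes. In genes shorter than the sequenced inserts, background reads need not follow gene length. The setting therefore cannot decide whether such short RNA genes are lower beyond background. At 4-fold, 8 genes were higher, namely kw2_0391, kw2_2209, comGF, comGE, radA, comGC, comGD and dprA, and 12 were lower. The added reads raised comGE, with 26 reads against 3, by construction. Its log2 ratio was 3.80 there and 2.34 with the rescaling alone.

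**Figure D3:**
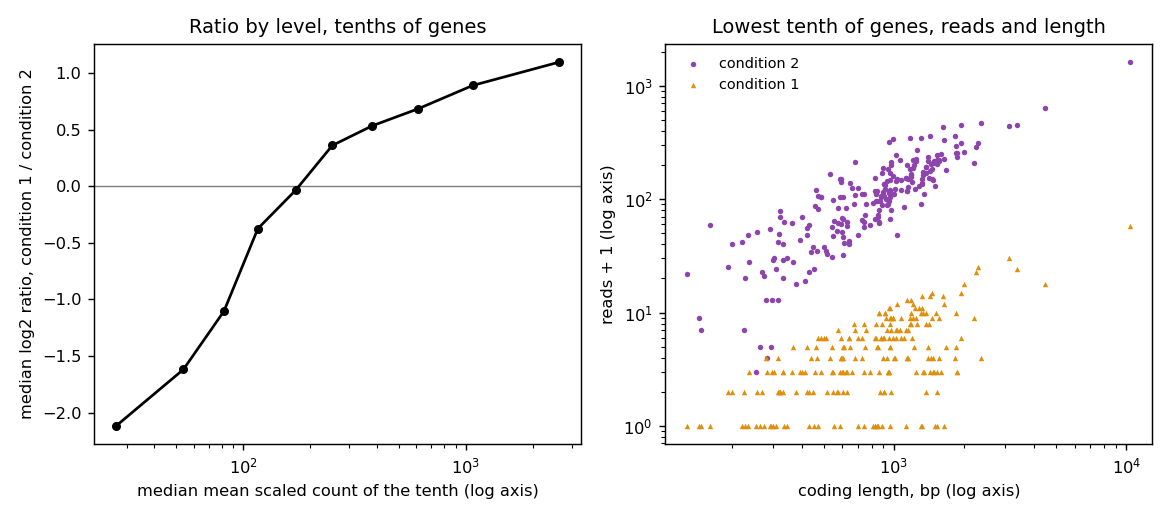
Left, median log2 ratio of condition 1 over condition 2 (y) in 10 equal groups of genes ordered by mean scaled count (x, log axis), from -2.12 to 1.096. Right, reads plus 1 (y, log axis) against coding length in bp (x, log axis) of the 225 protein-coding genes with the fewest condition 1 reads per kb. Condition 2 (circles) increases with length, at a median of 128 reads per kb. Condition 1 (triangles), by whose low values the genes were chosen, has a median of 4.53.

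Of the lists of amino acid synthesis genes, none had a member at least 2-fold higher in condition 1 with the authors' scaling. In arginine metabolism 4 of 9 measured genes were at least 2-fold lower, argJ by 7.94-fold (4.42 to 15.7) and argB by 5.81-fold (3.02 to 12.5). The list's median log2 ratio was -0.43, at percentile 1.27, and it moved to -0.021 and percentile 30.5 with the equal background. With a minimum scaled count of 100 the median of the 6 genes left was 0.43. In the synthesis of histidine, tryptophan and branched-chain amino acids 9 of 19 genes were at least 2-fold lower, hisC by 17.8-fold and hisG by 17.4-fold. Their median of -0.79 lay at percentile 53.7 and turned to 0.46, at percentile 100, with the equal background. The reads added to condition 1 raise the ratios of genes near 0 there by construction, and argJ, hisC and hisG are among the 225 genes that set the background. The values of hisC and hisG rest on 5 and 2 reads in condition 1.

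Purine synthesis genes had a median log2 ratio of 0.90, at percentile 96.3, with 6 of 16 at least 2-fold higher. guaC, the GMP reductase gene, was 3.79-fold higher and purE 3.28-fold. With the equal background the purine median was 0.34, at percentile 99.97, and 1 of 16 reached 2-fold, as did 1 of 16 with scaling by total count, where the median was 0.095. None of the 6 pyrimidine genes reached 2-fold, and pyrH had a ratio of 1.94 and pyrR of 1.84. The pyrimidine median of 0.81 lay at percentile 95.9, and it was 0.0070 with scaling by total count and 0.16, at percentile 82.4, with the equal background. All 4 measured genes of the ATP synthase passed 2-fold, with ratios of 2.66 for atpB and 2.65 for atpF, and the median of 1.33 lay at percentile 97.1. None of the 4 reached 2-fold with scaling by total count, where the median was 0.52, or with the equal background, where it was 0.39 at percentile 97.2. The ribosomal protein genes had a median of 1.07, at percentile 98.5, with 33 of 51 at least 2-fold higher, among them rplB at 3.13 and rplJ at 3.003. That percentile was 86.6 with the equal background, and none of the 51 reached 2-fold there or with scaling by total count.

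In the main setting the medians of 6 lists lay outside the central 95% of the matched random lists. These were late competence, DNA processing, ribosomal proteins, arginine, rRNA and tRNA, and the medians of all other measured lists lay inside. The tRNA median lay inside with no minimum, at percentile 2.585, and with the authors' DESeq2 fold changes, at percentile 15.5. Relative to genes of the same mean level 8 lists lay outside, with DNA damage at percentile 0.85, synthetases at 1.51 and purine at 98.3 added and arginine, at 8.58, inside. In the chaperone, glycolysis, peptide, fatty acid, cell wall and general stress lists, groES, groL and pepF alone stayed at least 2-fold higher with scaling by total count and with the equal background. Chaperones and heat shock genes had a median of 1.15 (percentile 93.4) with 5 of 9 above 2-fold, led by groES and groL. Glycolysis and pyruvate genes had a median of 1.09 (percentile 82.6), with pyk, the pyruvate kinase gene, at 3.11-fold and pflA at 2.56-fold. Peptide uptake and peptidase genes had a median of 1.11 (percentile 91.7), with pepF at the upper end and oppB, 8.71-fold lower, at the other. oppB rests on 8 reads against 114, is among the 225 genes that set the background, and turned to a log2 ratio of 3.01 with the background subtracted and 0.18 with it added to condition 1. Fatty acid genes had a median of 0.99 (percentile 83.0), with fabI at 3.08-fold and fabZ at 2.25-fold. Cell wall genes had a median of 0.84 (percentile 95.3), with dltC at 2.18-fold and murB at 2.08-fold. The peroxide reductase genes ahpC and ahpF, at 3.14-fold and 2.36-fold, led the general stress list, whose median was 1.22 (percentile 79.0).

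DNA damage and repair genes outside transformation had a median of 0.56, at percentile 6.44, and 2 of 18 passed 2-fold, ligA at 2.07 and recN at 2.03. Aminoacyl-tRNA synthetase genes had a median of 0.76, at percentile 14.8, with lysS at 2.49 and gltX at 2.002. With scaling by total count these 2 medians were -0.24 and -0.046. All 19 rRNA genes and 19 of 24 measured tRNA genes were at least 2-fold lower in condition 1. The reference biotype gave 61 tRNA genes, of which these 24 reached the minimum scaled count. With no minimum, 38 of 48 tRNA genes were at least 2-fold lower, and the median of -2.67 lay at percentile 2.585. With the shrunken fold changes of the authors' deposited table from DESeq2, 10 of 24 were lower, and the median lay at percentile 15.5. With the equal background the median log2 ratio of the rRNA genes was 0.080, at percentile 63.5, but 7 of the 19, all rrf genes, were still at least 2-fold lower, with log2 ratios from -2.41 to -1.39. The median of the tRNA genes was then -1.85, below all 10000 random lists. The background was added in proportion to gene length, and it may be too small for genes as short as the tRNA and rrf genes. Their values in this setting therefore do not show that they stay lower once background is equal. An rrf gene for 5S rRNA, kw2_2245, had 0 reads against 84 and was at least 17.1-fold lower. The rRNA gene kw2_2208 had 1 read against 144, and the tRNA genes kw2_0027 and kw2_1556 had 0 against 78 and 1 against 159. The rRNA genes are near-identical copies, so their reads may have been split or discarded in the authors' counting, and their values are uncertain. The RNA was also depleted of rRNA, leaving 303 rRNA reads in condition 1 and 3571 in condition 2. A difference in depletion between the 2 libraries cannot be told apart from a difference in level.

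Neighbouring genes often differed in the same direction. There were 26 runs of at least 3 neighbouring genes that were all at least 2-fold higher in condition 1, where 95% of 10000 shuffles of the gene order gave 3 to 13. There were 58 runs of lower genes, where shuffles gave 15 to 31. The shuffles do not account for level, and relative to genes of the same mean level there were 7 runs of higher and 34 of lower genes. With the background subtracted there were 5 and 20, and with the equal background 4 and 1. These settings call fewer genes and had no shuffles of their own, so their runs cannot be set against the ranges above. The longest run of higher genes held 9, kw2_2177 and kw2_2178 with the 7 comG genes, with log2 ratios from 1.07 to 4.92. A run of 8 genes held the ATP synthase genes, and a run of 6 genes ended with kw2_0391, groES and groL. The longest run of lower genes held 15, from kw2_0790 to kw2_0804, and included gtfA, gtfB, secY2 and asp1 to asp3, genes of an accessory secretion system, as well as kw2_0799.

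The authors analysed the same 2 libraries with 3 methods, and their p-values rest on 1 library per strain. In the authors' deposited table from edgeR, 440 of 2331 genes had an adjusted p of at most 0.05, 35 with a positive and 405 with a negative log2 fold change. The positive sign there is condition 1 over condition 2. In the authors' deposited table from DESeq2 none of the 171 genes with an adjusted p reached 0.05, the smallest value was 0.0619, and 79 genes had an unadjusted p under 0.05. The authors' deposited table from DEXUS flags 1963 genes as informative, and these include all 440 genes of the edgeR table. For comGF, radA and dprA the adjusted p in the authors' deposited table from edgeR was 2.0e-07, 1.3e-06 and 0.00019, and for recA 0.055. The sign of the fold change was the same in all 3 tables for 2253 of the 2331 genes they share. Of the genes that DEXUS flags as informative, 1104 had a positive and 859 a negative log fold change. The flag covers most genes, among them genes with small ratios. Its signs therefore cannot be set against those of the edgeR calls.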

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

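The settings that treat background reads, the rescaling alone and the one relative to genes of the same mean level, were chosen after seeing the data; the others were set out in advance. The late competence list stayed at a positive median under every setting run, from 1.62 to 3.59. It was 2.67 with total-count scaling, 2.38 with a pseudocount of 5 and 1.62 in the shrunken fold changes of the authors' deposited table from DESeq2. With the same background added to condition 1 it was 2.89, and relative to genes of the same mean level 3.04. The counts of genes moved more. With total-count scaling 38 genes were at least 2-fold higher, 844 at least 2-fold lower and 9 at least 4-fold higher, because the scaling lowers the ratios. With the fold changes of the authors' deposited table from DESeq2, 197 genes were 2-fold higher, 10 were 4-fold higher and 80 were 4-fold lower, since those values are shrunken. With a minimum of 100, which tests fewer genes, 284 genes were 2-fold lower and 186 were 4-fold lower, and the median of the tRNA genes turned to 0.32 in fewer genes. The number of gene lists outside the central 95% of random lists was 4 there, against 6 in the main setting and 8 relative to genes of the same mean level. Runs of at least 2 genes numbered 78 higher and 111 lower, and at 1.5-fold 105 runs were higher.

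With the background subtracted from condition 2, 183 genes were 2-fold higher and 266 lower, 92 were 4-fold higher and 144 lower, in 5 runs of higher and 20 of lower genes. Of the 371 genes at least 2-fold higher in the main setting, 55 were also higher there. argJ turned to 1.01, argB to 3.30, hisG to 1.47, oppB to 3.01 and kw2_2208 to 0.91. These genes had few reads in condition 1. Their 57 to 156 reads in condition 2 fell to or near 0 by the subtraction. None of them reached the minimum scaled count of 20 in that setting. With the same background added to condition 1, 54 genes were 2-fold higher and 53 lower, 8 were 4-fold higher and 12 lower, in 4 runs of higher and 1 of lower genes. There, 39 of the 371 higher genes and 50 of the 552 lower genes kept their call. The median of the rRNA genes turned to 0.080, argJ to 0.047, argB to 0.29, hisG to 0.51, kw2_1264 to 0.031, xylB to 0.56, oppB to 0.18, kw2_1932 to 0.30 and kw2_2208 to 0.46. Relative to genes of the same mean level, 244 genes were 2-fold higher and 362 lower, 59 were 4-fold higher and 192 lower, in 7 and 34 runs, and gltX turned to -0.068. With the rescaling alone, which lowers the ratios, 22 genes were 2-fold higher and 975 lower, 8 were 4-fold higher and 549 lower, in 4 and 119 runs, and the late competence list was 2.34. The regulator list turned to -0.0065, ligA to -0.015, the spx gene kw2_0494 to -0.0065, recN to -0.041, murB to -0.0055 and gltX to -0.063. The cause of the changes without a stated reason was not tested.

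Of 746 values of 68 named genes under these settings, 30 changed sign. In 19 the gene was at least 2-fold apart in the main setting, none of them under a setting set out in advance. The other 11 were values of clpB, recR, the spx gene kw2_0616, pyrR and pyrH, and 3 of these came with total-count scaling. Not run were TMM scaling, which needs deposited counts, the motif search, which needs a genome, and any setting for comX, which has no row. Matching lists by symbol only is what the main setting does. No replicate could be left out. No paired analysis was possible because there is 1 library per strain. At this depth a gene with 3 reads has 3.84 scaled counts in condition 1 and 2.35 in condition 2, and differences of genes near these values were not detectable.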

Other observations

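The tests of the exchanged numbering, of the proportion of background to gene length, of depth, of a wrong scaling factor and of groES and groL, and the count of the same genes after subtraction, were chosen after the result was seen. The genes named in this and the next paragraph were chosen after their values were seen. Next to the competence genes, several genes were at least 2-fold higher in condition 1 with the authors' scaling and also with the equal background. That setting adds reads to condition 1, and with its rescaling alone kw2_1750, kw2_1004 and liaF were not 2-fold higher. kw2_1750 and kw2_1751 were 4.01-fold (3.56 to 4.52) and 4.33-fold (3.05 to 6.24) higher, and kw2_1577, next to ffh, was 4.47-fold higher (4.17 to 4.79). kw2_1703 and kw2_1705 are the neighbours of pepF, and kw2_1004, next to radC, was 3.54-fold higher (3.04 to 4.13). liaF was 4.10-fold higher (3.68 to 4.58). The folds in this paragraph are with the authors' scaling.

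Of the 27 protein-coding genes 2-fold lower in condition 1 with the equal background, some had many reads in condition 2. kw2_1372 had 47 reads against 929 and was 12.1-fold lower (9.01 to 16.6), kw2_1291 had 28 against 1174 and was 25.6-fold lower (17.6 to 38.7), and kw2_1311 had 219 against 2859 and was 7.98-fold lower (6.95 to 9.20). dhaK and dhaL, genes of dihydroxyacetone kinase, were 2.01-fold (1.74 to 2.33) and 2.93-fold (2.24 to 3.87) lower. These folds are with the authors' scaling. With the equal background the log2 ratios were -2.64 in kw2_1372, -1.87 in kw2_1291, -1.72 in kw2_1311 and -1.34 in both dhaK and dhaL. kw2_0799 has no length in the reference and could not be tested in that setting.

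The first pattern is that late competence genes were higher in condition 1, which the assignment columns give to the control library. All 7 measured late competence genes were at least 2-fold higher there. A candidate explanation is that the condition numbers and the libraries were exchanged in the deposited table, since ComX is known to turn these genes on. A table that names its numerator would decide, and none does, so an exchange and a control library with high competence genes cannot be told apart from these tables. The size of the difference does not depend on this, with a list median of 2.89 with the equal background.

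The second pattern is the excess of genes at least 2-fold lower in condition 1, mostly genes of low level. The tables argue against different depth, because condition 1, where the lower genes had fewer reads, was the deeper library with 1.07 times the reads of condition 2. They also argue against a single wrong scaling factor as the only cause, because the medians of groups of genes by level differ by 3.21. The number of lower genes still depends on the scaling, and was 844 with scaling by total count. Background reads in condition 2 remain a candidate explanation, since across the 225 genes with the fewest condition 1 reads per kb, which are not independent replicates, Spearman's rho of condition 2 reads and length was 0.876 (0.833 to 0.906), although it was 0.549 in condition 1 too. Whether a constant background accounts for most of the lower genes stays open. Subtraction gave 168 lower protein-coding genes outside those 225 (161 to 190) where there were 304, above a bound of 152 set in advance. This count includes genes not lower before. Of the 304 themselves 137 stayed lower (130 to 160) and 86 were no longer measured. With the equal background 21 protein-coding genes outside those 225 were lower, but that setting adds reads to condition 1 by construction. Of all 552 lower genes of every gene type, 233 stayed lower after subtraction and 229 were no longer measured. Genomic DNA of growing cells may be a source, since the 57 such genes nearest to the origin by tag order had 1.51 times the reads per kb of the farthest 57 (1.20 to 1.78), but from near to far the medians of the 4 groups were 156, 120, 130 and 104, not a steady fall, and these genes gave 1.63 in condition 1 too, the RNA was treated with DNase, and low-level transcription was not tested.

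The third pattern is groES and groL at 6.76-fold and 4.71-fold higher in condition 1, next to kw2_0391. A general heat shock response is one candidate explanation, and hrcA, grpE and dnaK lay 0.29, 0.84 and -0.15 above genes of the same level on the log2 scale, with a median of 0.29, against 1.65 for groES and 1.12 for groL. These 3 genes are too few and too spread to exclude it. Transcription from kw2_0391 that runs on into groES and groL is another, and the log2 ratio fell in 3 of 3 steps, from 5.59 over 2.76 and 2.23 to 0.21 in kw2_0394. Strand and the reads between the genes are not in these tables, so this also stays open. The effect of ComX, or of its absence, on these genes was not tested apart from both.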
